A study of Mus musculus with 6 samples.

How the data were processed

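RNA-seq libraries of cultured mouse chondrocytes were compared between 3 WT and 3 Ppp1r15b KO samples, grouped by their titles. The series design text reads as RNA taken straight from the sorted cells, whereas the growth protocol in the labels adds a culture step until the cells matured. Per the labels' protocols, STAR 2.7.5a placed read pairs on the genome build mm10, genes were those of GENCODE vM25, and featureCounts 2.0.0 counted them. Groups were then compared with DESeq2 1.28.1 with an adjusted p under 0.05 and an absolute log2 fold change above 0.585. FastQC and MultiQC are also named there.

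The tables used here do not hold what that protocol would give. The deposited gene table gives estimated counts, 12.9% of them not whole numbers, under Entrez gene identifiers, and the deposited transcript table gives estimated counts for 56077 RefSeq transcripts, whose sums per gene match the gene table to within 0.04 counts. Both deposited tables also give TPM values and FPKM values, scaled for length and depth by the authors; the TPM of Ppp1r15b alone was read, and the FPKM values were not used here. The counting program, annotation release and strand setting of these tables are not given in the sources used here. Reads that match several genes can be split by such a counter, so genes with near-identical copies (Rps6, clustered protocadherins) are uncertain. Of the 17666 gene identifiers, 17551 matched a RefSeq gene table of GRCm38.p6, the build that mm10 stands for, which with the GENCODE vM21 annotation of the same build gave the position of Ppp1r15b.

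The estimated counts were rounded to whole numbers, as fixed in advance for this unit. Library totals were 19643951, 18854890 and 18757808 for WT replicates 1 to 3 and 18478991, 18380880 and 19581607 for KO replicates 1 to 3. The common dispersion was 0.0525, a coefficient of variation of 22.9%. Intervals from counts cover counting error only. Pairs of libraries within a group differed by more than sampling noise. The chi-square per degree of freedom was 3.12 between WT replicates 1 and 3 and 5.01 between KO replicates 1 and 2. For the other pairs it was 16.1 to 134. All 6 were kept as separate samples, though such a difference cannot show that they came from separate animals or cultures.

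Analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the package data.table (1.17.8). Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), scaled by TMM and fitted without covariates by the edgeR quasi-likelihood method, with a two-sided test of KO against WT and Benjamini-Hochberg adjustment over 13692 genes. The standard error of a log2 fold change was its size over the square root of the F statistic. Fold changes of genes with few counts in KO depend on the prior count and are no bounds. CPM values used TMM-scaled library sizes, and log2 CPM values a prior count of 2. Rose and fell mean an adjusted p under 0.05.

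Before the data were examined, 29 gene lists of 543 genes were fixed, of which 534 were in the gene table and 28 lists had at least 5 tested members. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists. Their members were counted by the gene test, adjusted over all genes and over the list alone. The rule for named genes was also fixed before. It took Ppp1r15b, the 10 largest rises and falls and the 3 smallest p in each direction among called genes with a mean log2 CPM above 1, no overlap of groups and no predicted or pseudogene symbol, and from each list up to 2 called members with the largest change in each direction or, with none called, the 2 most abundant. For 1 gene that this rule took, the result is not reported here. Further genes named from a list's called members, and those of the closing part, were chosen after their values were seen.

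Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, library size only, the DESeq2 Wald test, limma-voom, no filter beyond 1 count, a filter of at least 1 CPM in all 6 libraries, the replicate number as a block, each library left out in turn, and for lists an estimated correlation, fry and the removal of genes held by several lists. Robust quasi-likelihood, limma-voom with library quality weights, and WT replicate 2 and KO replicate 3 both left out were added after seeing the data. The scripts were tested on simulated data drawn from the means and library sizes of these libraries. At the dispersion of all 6 libraries, 55% of 100 genes changed 2-fold and 95% of 100 genes changed 4-fold were recovered among 13542 genes, with 6 false calls. At the dispersion without KO replicate 3, 95% and 100% were recovered among 13597 genes, with 15 false calls. That run still drew 3 WT and 3 KO libraries, so these rates are not those of the fit without KO replicate 3. With no change 0 of 28 lists were called. Genes were drawn independently of each other there, so this cannot show how often camera calls lists of correlated genes.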

Results

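RNA was sequenced from cultured mouse chondrocytes to compare cells that carried Ppp1r15b with cells from which it had been deleted in the limb skeleton. Ppp1r15b encodes CReP, the constitutive regulatory subunit of the phosphatase that removes phosphate from the translation factor eIF2alpha. Per the labels, chondroprogenitors were sorted by GFP from digested knee joints of newborn (P0) mice, either Prx1-Cre with the Rosa26 mT/mG reporter (WT) or the same with Ppp1r15b deleted by Prx1-Cre (KO), and were cultured until mature. Prx1-Cre acts in early limb mesenchyme, and the reporter turns green where Cre has acted. The series title places the study in lipid metabolism of chondrocytes and skeletal growth. There were 3 WT and 3 KO libraries, with 18757808 to 19643951 estimated counts per WT library and 18380880 to 19581607 per KO library. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

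Ppp1r15b (Entrez gene 108954) lay lower in every KO library than in every WT library. Its level was 76.1 ± 20.7 CPM in WT and 23.4 ± 4.13 CPM in KO (SD, n = 3 each), a log2 fold change of -1.70 (SE 0.242, edgeR adjusted p = 0.0297). The counts were 1707, 960 and 1675 in WT replicates 1 to 3 and 355, 428 and 557 in KO replicates 1 to 3. WT replicate 2 therefore held 68.7% of the WT mean, and the KO libraries held 25.4%, 30.9% and 36.2% of it. The gene lies on chromosome 1 from 133131166 to 133139800 in GRCm38.p6, and the GENCODE annotation of the same build gives it 2 exons and 1 transcript. The labels do not name the deleted part, so the counts left in KO are described as remaining counts only. Without WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 2 the call was lost (adjusted p = 0.168, 0.173, 0.118 and 0.13), with log2 fold changes of -1.59, -1.57, -1.57 and -1.70.

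**Figure D1:**
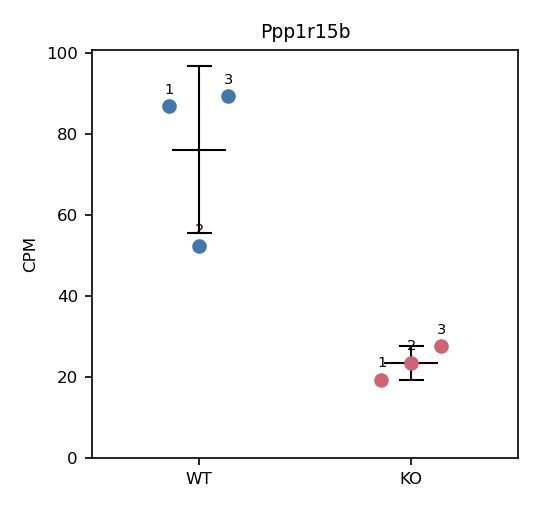
Ppp1r15b in CPM (vertical axis, from 0) per library for WT and KO. Points are libraries with their replicate numbers, the horizontal bar is the mean and the whiskers are 1 SD (n = 3). The WT libraries lie from 52.2 to 89.2 CPM and the KO libraries from 19.3 to 27.5 CPM.

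In KO, 9 of 12 tested adipocyte genes fell, and 13 of 32 tested targets of the stress transcription factors ATF4 and CHOP rose while 19 were not called, Atf4 itself among these (0.52, edgeR adjusted p = 0.0622). Both lists were called by camera at a preset correlation and lost at an adjusted p = 0.35 with an estimated correlation. The mean log2 fold change was -3.72 over the adipocyte list, beside -2.51 over macrophage and -2.15 over skeletal muscle genes. Adipoq, which encodes the fat hormone adiponectin, fell from 151 ± 49.7 to 3.03 ± 0.681 CPM (SD, n = 3 each). Cth, an enzyme of cysteine synthesis and an ATF4 target, rose from 24.3 ± 3.49 to 58.8 ± 2.39 CPM. Of the 13692 genes tested, 121 rose and 223 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test), and 77 rose and 198 fell when a log2 change over 0.585 was also required. At an unadjusted p under 0.05 there were 2627 genes. In 3894 genes (28.4%) all KO libraries lay on the same side of all WT libraries, where chance gives 10%.

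Among genes that rose, Kif21b, a kinesin motor, had the smallest p, with a log2 fold change of 1.36 (SE 0.0732, adjusted p = 0.0112). The osmolyte transporter gene Slc5a3 rose by 0.96 (SE 0.071, adjusted p = 0.0126). Other large rises were in Hoxb9 (1.79), Prss12 (1.76), Prdm6 (1.75), Ccdc3 (1.72), Pdzd7 (1.67), Ostn (1.61), Trim66 (1.56) and Soat2 (1.53). Pcdhgb8 (2.45) and Rps6 (1.89) also rose, but both are uncertain. Pcdhgb8 shares constant exons with the rest of its gene cluster, and Rps6 has many processed copies. Among called genes with a mean log2 CPM above 1, the largest falls were in Cfd, the complement factor adipsin (-7.66, SE 0.612, adjusted p = 0.0126), Adipoq (-5.63), Slc36a2 (-5.07), the beta-3 adrenergic receptor gene Adrb3 (-5.01), Thrsp (-4.66), Fabp4 (-4.53), Lrg1 (-4.53), Gpd1 (-4.51), Plin1 (-4.36) and Tshr (-4.0). Cidec (-6.65) and Retn (-6.06) also fell by as much, at a lower mean level. Cav1, the main coat protein of caveolae, fell from 416 ± 49.3 to 130 ± 5.01 CPM (SD, n = 3 each), a log2 fold change of -1.68 (SE 0.106, adjusted p = 0.0112), and Apcdd1, a Wnt inhibitor, fell by 1.67 (SE 0.111, adjusted p = 0.0112).

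The number of calls depended on single libraries. Without KO replicate 3, 1731 genes rose and 2231 fell, without WT replicate 2 the counts were 37 and 139, and without any other library 0 genes were called (1555, 1572, 2345 and 2128 genes at an unadjusted p under 0.05 without WT replicate 1, WT replicate 3, KO replicate 1 and KO replicate 2). KO replicate 3 stood apart: log2 CPM values correlated across genes at r = 0.9935 between KO replicates 1 and 2 and at 0.9346 and 0.9337 between each of these and KO replicate 3, and WT replicate 2 lay on the KO side of the other WT libraries. The first principal component held 56.2% of the variance and parted the groups by a narrow gap only, between KO replicate 3 (-11.7) and WT replicate 2 (-13.6). All 344 called genes kept their direction without KO replicate 3 and all were called again there. The groups did not overlap in any of these 344 over the 6 libraries, so their direction could hardly turn. With both KO replicate 3 and WT replicate 2 left out, a setting chosen after seeing the data, 2416 genes rose and 3000 fell, with all 344 among them. The pairs then left had common dispersions of 0.0014 (WT replicates 1 and 3) and 0.00304 (KO replicates 1 and 2). Other pairs within a group had 0.0194 to 0.148, so these counts rest on the spread within close pairs only.

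**Figure D2:**
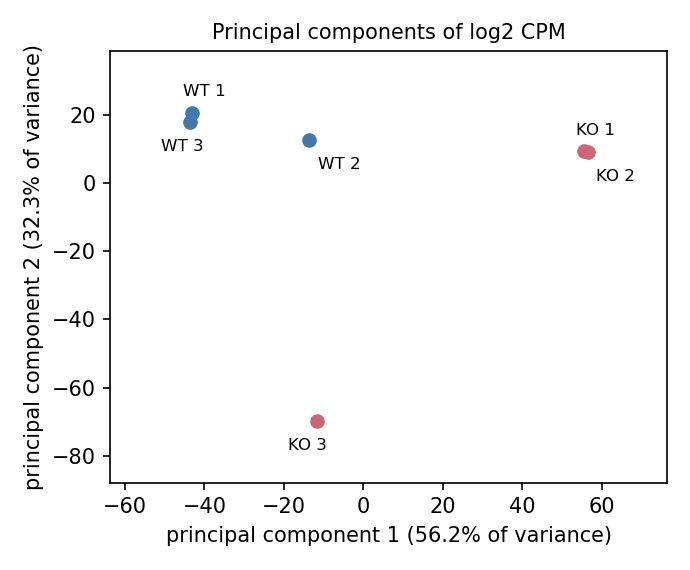
First and second principal component of log2 CPM over 13692 genes, with the share of variance on each axis (56.2% and 32.3%). Points are libraries. WT replicates 1 and 3 lie at -43.3 and -43.6 and KO replicates 1 and 2 at 55.6 and 56.5 on the first component, while KO replicate 3 lies at -69.8 on the second.

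ATF4 and CHOP targets of the integrated stress response, the programme that follows eIF2alpha phosphorylation, were called higher as a list (camera adjusted p = 1.12e-16, adjusted p = 0.35 with an estimated correlation). Of 32 tested members 13 rose, 0 fell and 19 were not called, and 24 rose and 0 fell when adjusted over the list alone. All 32 had a higher estimate in KO. The largest rises were in Soat2 (1.53, SE 0.268, adjusted p = 0.0483), the stress hormone Fgf21 (1.29, SE 0.225, adjusted p = 0.0481) and Cth (1.27, SE 0.115, adjusted p = 0.0136). The amino acid transporter subunits Slc7a5 (0.88) and Slc3a2 (0.71), Slc7a3 (1.12), the glutathione-degrading enzyme Chac1 (0.78) and Vldlr (0.80) rose as well, as did Trib3, Atf5, Gpt2, Sesn2 and Vegfa. The mean over the list was 6.17 ± 0.131 log2 CPM in WT and 6.85 ± 0.257 in KO (SD, n = 3 each). It was 6.08, 6.32 and 6.11 in WT replicates 1 to 3 and 6.72, 6.69 and 7.15 in KO replicates 1 to 3. WT replicate 2 was thus the WT library nearest to KO. Whether the rise of this list reflects cell makeup or expression per cell was not tested. With KO replicate 3 left out, 26 members rose and 2 fell.

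Genes of serine, glycine and one-carbon synthesis were called higher by camera (adjusted p = 0.00119, adjusted p = 0.35 with an estimated correlation). Of 12 tested, Phgdh, the first enzyme of serine synthesis (0.68, SE 0.119, adjusted p = 0.0481), and mitochondrial Mthfd2 (0.52, SE 0.0832, adjusted p = 0.041) rose, 0 fell and 10 were not called; adjusted over the list alone, 3 rose and 1 fell. Of 20 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, Lars (0.77, SE 0.132, adjusted p = 0.0466) and Aars (0.49, SE 0.0753, adjusted p = 0.0361) rose, 0 fell and 18 were not called, against 9 that rose and 0 that fell when adjusted over the list alone. That list was called higher (camera adjusted p = 6.98e-05, adjusted p = 0.462 with an estimated correlation). Of 25 endoplasmic reticulum chaperones and unfolded protein response genes, 0 were called over all genes and 0 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.106). Its most abundant members were P4hb (-0.16, adjusted p = 0.376) and Calr (-0.32, adjusted p = 0.136). Without KO replicate 3, 2 of the 25 rose and 8 fell, Calr among these (-0.28, adjusted p = 0.013), and the list was not called by camera (adjusted p = 0.0952). The spliced form of Xbp1, made by the stress sensor IRE1, took 4.06 ± 1.53% of Xbp1 estimated counts in WT and 5.55 ± 3.52% in KO (SD, n = 3 each; two-sided exact permutation p = 0.7, where 0.1 is the smallest possible). Its share was 9.6% in KO replicate 3. In KO replicates 1 and 2 it was 3.82% and 3.22%, within the WT range of 2.48% to 5.53%. Among serine and glycine genes 5 rose and 1 fell without KO replicate 3, and 9 synthetases rose and 0 fell.

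**Figure D3:**
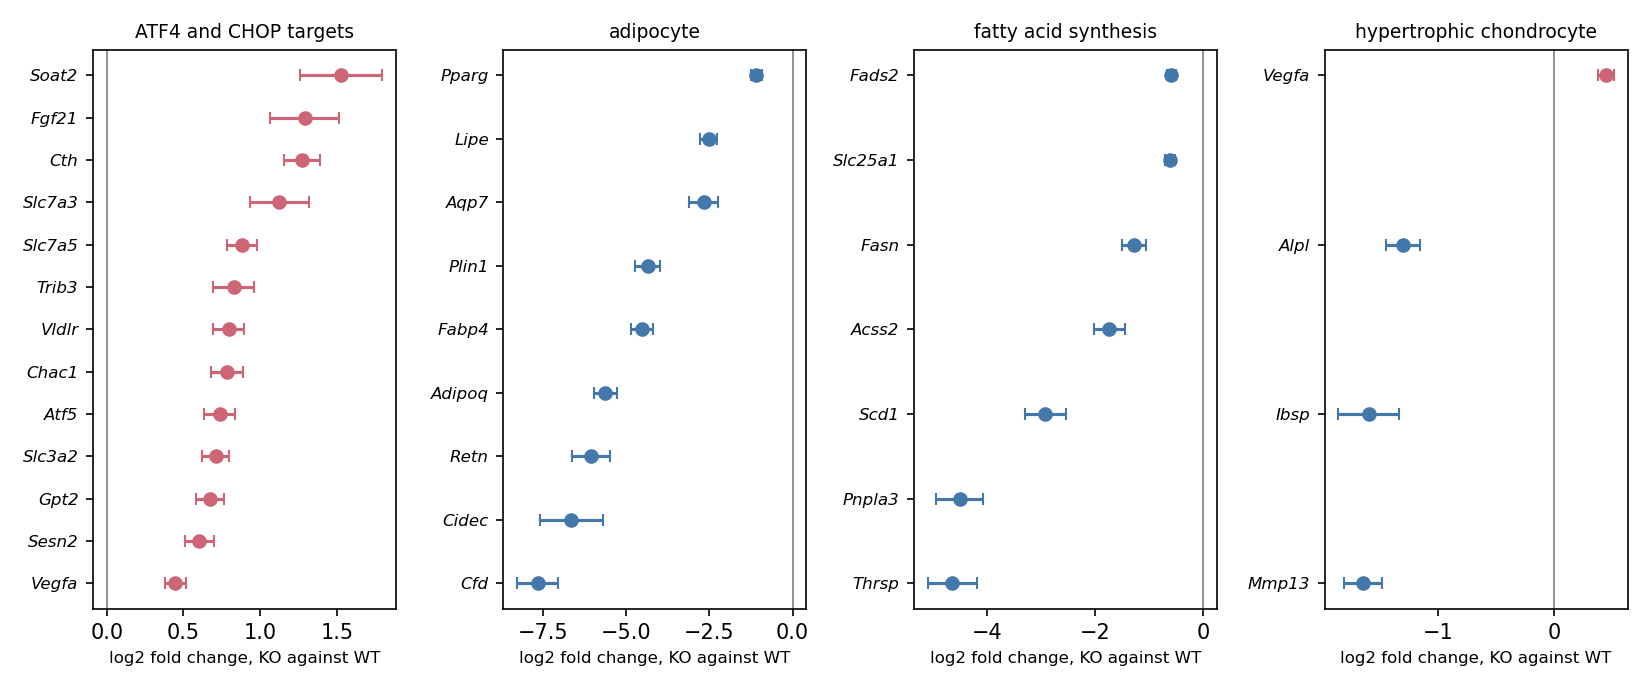
Log2 fold change, KO against WT, of the called members of 4 fixed lists (horizontal axis, a separate scale per panel). Points are edgeR estimates and whiskers 1 SE. The ATF4 and CHOP targets shown lie from 0.45 to 1.53, the adipocyte genes from -7.66 to -1.09, the fatty acid synthesis genes from -4.66 to -0.59, and in the hypertrophic list Vegfa lies at 0.45 and Mmp13 at -1.64.

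Over all 6 libraries adipocyte genes had the lowest list mean of log2 fold changes (-3.72), beside macrophage (-2.51) and skeletal muscle genes (-2.15). Without KO replicate 3 muscle (-4.67) and macrophage genes (-4.09) lay below adipocyte genes (-3.96). Of 12 tested, 9 fell, 0 rose and 3 were not called, and all 12 fell when adjusted over the list alone. The lipid carrier gene Fabp4 fell from 300.0 ± 97.9 to 13.0 ± 2.97 CPM, the lipid droplet coat gene Plin1 from 66.6 ± 23.6 to 3.25 ± 0.859 CPM, and Cfd from 72.0 ± 28.7 to 0.340 ± 0.310 CPM (SD, n = 3 each). Pparg, the master regulator of fat cell formation, fell by 1.09 on the log2 scale (SE 0.175, adjusted p = 0.0404). For Cidec, a lipid droplet fusion protein, 342 counts in WT stood against 3 in KO, a ratio of 114 (95% counting interval 38.7 to 556). Camera called the list lower (adjusted p = 1.47e-14, adjusted p = 0.35 with an estimated correlation). The list mean was 6.11, 5.12 and 5.91 log2 CPM in WT replicates 1 to 3 and 2.32, 2.28 and 2.11 in KO replicates 1 to 3.

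Fatty acid synthesis and desaturation genes were called lower (camera adjusted p = 1.67e-05, adjusted p = 0.35 with an estimated correlation). Of 20 tested, 7 fell, 0 rose and 13 were not called; adjusted over the list alone, 8 fell and 1 rose. Thrsp (-4.66, SE 0.452, adjusted p = 0.0149) and Pnpla3 (-4.52, SE 0.435, adjusted p = 0.0149) fell most. Scd1, the main desaturase, fell from 1698 ± 633 to 224 ± 64.7 CPM, and fatty acid synthase, Fasn, from 766 ± 215 to 316 ± 29.6 CPM (SD, n = 3 each), and Acss2, Slc25a1 and Fads2 fell as well. Triacylglycerol synthesis, lipid droplet and lipolysis genes were also called lower (camera adjusted p = 1.01e-05, adjusted p = 0.35 with an estimated correlation). Of 21 tested, Cidec (-6.65), hormone-sensitive lipase Lipe (-2.52, SE 0.249, adjusted p = 0.0154), adipose triglyceride lipase Pnpla2 (-2.22), Agpat2 (-2.01) and Dgat1 (-0.76) fell, 0 rose and 16 were not called, against 12 that fell and 1 that rose when adjusted over the list alone. Cidec and Lipe also stand in the adipocyte list. With genes held by several lists left out, the triacylglycerol list was called over 18 genes (camera adjusted p = 0.000662). With KO replicate 3 left out, 10 fatty acid synthesis genes fell and 1 rose, and 15 triacylglycerol genes fell and 1 rose.

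Fatty acid uptake and oxidation genes were called lower (camera adjusted p = 0.00498, adjusted p = 0.372 with an estimated correlation), although members moved both ways. Of 30 tested, the acyl-CoA synthetase Acsl1 fell (-2.60, SE 0.249, adjusted p = 0.0149), the mitochondrial coactivator Ppargc1a rose (1.20, SE 0.141, adjusted p = 0.0195), and 28 were not called; adjusted over the list alone, 5 fell and 1 rose. Of 25 cholesterol genes, Ebp, a sterol isomerase, fell (-0.53, SE 0.0801, adjusted p = 0.034), 0 rose and 24 were not called, against 4 that fell and 0 that rose when adjusted over the list alone. The cholesterol list was not called (camera adjusted p = 0.0623), and its mean log2 fold change (-0.09) and median (0.04) differed in sign. The list: cholesterol biosynthesis and uptake, was called lower without WT replicate 2 (camera adjusted p = 0.0395) and without KO replicate 3 (1.7e-05, adjusted p = 0.536 with an estimated correlation), where 16 members fell. It was past the threshold in 4 of 17 alternatives (adjusted p from 5.04e-06 to 0.699). Of 24 phospholipid and sphingolipid genes 0 were called, against 4 that rose and 1 that fell when adjusted over the list alone, and the list was not called (camera adjusted p = 0.218). In the phospholipid list 4 members rose and 1 fell without KO replicate 3. The most abundant members were Degs1 (0.30, adjusted p = 0.385) and Cers2 (0.38, adjusted p = 0.392). Of the uptake and oxidation genes, 11 fell and 1 rose without KO replicate 3.

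Chondrocyte matrix genes were called higher (camera adjusted p = 0.00188, adjusted p = 0.47 with an estimated correlation). The rotation test fry did not call this list (adjusted p = 0.23). Estimates were higher in 19 members and lower in 5, with Col2a1 at -0.22 (edgeR adjusted p = 0.617) and Sox9 at 0.06 (0.87). Of 24 chondrocyte genes, the cartilage collagens Col9a2 (from 187 ± 49.6 to 387 ± 18.5 CPM, SD, n = 3 each) and Col11a2 (from 1138 ± 166 to 1966 ± 118 CPM) rose, 0 fell and 22 were not called, and 6 rose and 0 fell when adjusted over the list alone. WT replicate 2, at 8.40 log2 CPM, lay near the KO mean of 8.47 ± 0.06, while WT replicates 1 and 3 lay at 8.01 and 7.92. Genes of hypertrophic chondrocytes, the terminal stage of the growth plate, were called lower (camera adjusted p = 0.00637, adjusted p = 0.35 with an estimated correlation). Of 13 hypertrophic genes, the collagenase Mmp13 (-1.64, SE 0.161, adjusted p = 0.0151), the mineral matrix protein gene Ibsp (-1.60, SE 0.26, adjusted p = 0.0417) and alkaline phosphatase Alpl (-1.30, SE 0.144, adjusted p = 0.0188) fell. Vegfa, an angiogenic factor that also stands among the ATF4 targets, rose (0.45, SE 0.0693, adjusted p = 0.0375), and 9 were not called. Adjusted over the list alone, 5 fell and 1 rose. Among chondrocyte genes 6 rose and 0 fell without KO replicate 3, and among hypertrophic genes 2 rose and 7 fell.

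Fibroblast, perichondrium and synovium genes were called lower (camera adjusted p = 0.012, adjusted p = 0.47 with an estimated correlation). Of 19 tested, the matrix protein gene Tnc (-0.55, SE 0.0781, adjusted p = 0.0297) and the intermediate filament gene Vim (-0.63, SE 0.112, adjusted p = 0.0489) fell, 0 rose and 17 were not called, with the same counts when adjusted over the list alone. The list: fibroblast, perichondrium and synovium, lost its call without KO replicate 3 (camera adjusted p = 0.597) and without WT replicate 1 (0.0617), and was past the threshold in 11 of 17 alternatives (adjusted p from 0.00251 to 0.665). Of 7 tendon and ligament genes Thbs4, a tendon matrix protein, fell (-1.67, SE 0.128, adjusted p = 0.0126), 0 rose and 6 were not called, against 1 that fell and 1 that rose when adjusted over the list alone, and the list was not called (camera adjusted p = 0.171). Of 9 osteoblast and osteocyte genes 0 were called by either adjustment (camera adjusted p = 0.478), with Col1a1 at -0.67 (adjusted p = 0.519) and Smpd3 at 0.74 (adjusted p = 0.437), whereas without KO replicate 3, 1 rose and 2 fell. Of 24 growth plate signalling genes 0 were called over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.739), with Igf2 at -0.14 (adjusted p = 0.836) and Igfbp5 at 0.65 (adjusted p = 0.581), whereas without KO replicate 3, 8 of the 24 rose and 4 fell. Of 14 matrix protease genes 0 were called by either adjustment (camera adjusted p = 0.0847), with Timp3 at 0.23 (adjusted p = 0.782) and Timp2 at 0.01 (adjusted p = 0.989). The list: matrix proteases and inhibitors, was called lower without KO replicate 2 (camera adjusted p = 0.0479; past the threshold in 2 of 17 alternatives, from 0.0479 to 0.35), and without KO replicate 3, 2 members rose and 5 fell. In that setting 6 fibroblast genes rose and 9 fell, and 2 tendon genes rose and 1 fell.

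Markers of cell types outside the Prx1 lineage were present in WT and varied between libraries. Macrophage and osteoclast genes, which a GFP sort of limb mesenchyme would be set to remove, had a list mean of 4.45, 3.53 and 4.47 log2 CPM in WT replicates 1 to 3 and 0.35, 0.26 and 2.68 in KO replicates 1 to 3. Of 15 tested, the complement gene C1qa (-4.66, SE 0.458, adjusted p = 0.0152) and Cd14 (-2.75, SE 0.326, adjusted p = 0.0195) fell, 0 rose and 13 were not called, and 8 fell and 0 rose when adjusted over the list alone (camera adjusted p = 2.73e-09, adjusted p = 0.35 with an estimated correlation). Skeletal muscle genes had a list mean of 5.00, 2.06 and 4.79 in WT and 0.05, 0.06 and 3.62 in KO. Of 13 muscle genes 0 were called by either adjustment, although camera called the list lower (adjusted p = 0.00074, adjusted p = 0.47 with an estimated correlation), with Acta1 at -2.02 (adjusted p = 0.468) and Myh3 at -2.40 (adjusted p = 0.381). Without KO replicate 3, 12 of the 13 muscle genes and 15 of the 15 macrophage genes fell (camera adjusted p = 0.00015 and 2.27e-10, adjusted p = 0.536 for both with an estimated correlation).

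Of 9 smooth muscle and pericyte genes Tagln, an actin-binding protein, fell (-1.23, SE 0.163, adjusted p = 0.0263), 0 rose and 8 were not called, against 4 that fell and 0 that rose when adjusted over the list alone (camera adjusted p = 0.00119, adjusted p = 0.35 with an estimated correlation). Of 11 endothelium genes 0 were called by either adjustment, while camera called the list lower (adjusted p = 0.034, adjusted p = 0.47 with an estimated correlation), with Eng at -0.27 (adjusted p = 0.248) and Erg at -0.50 (adjusted p = 0.163). The call of the list: endothelium, was lost without KO replicate 1 (camera adjusted p = 0.131), KO replicate 2 (0.152) or WT replicate 3 (0.0848), and it was past the threshold in 11 of 16 alternatives (adjusted p from 0.000987 to 0.47). Of the 8 erythroid genes 5 were listed and 0 reached the count filter, so that list was not tested. In each of the smooth muscle and endothelium lists 6 genes fell and 0 rose without KO replicate 3.

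**Figure D4:**
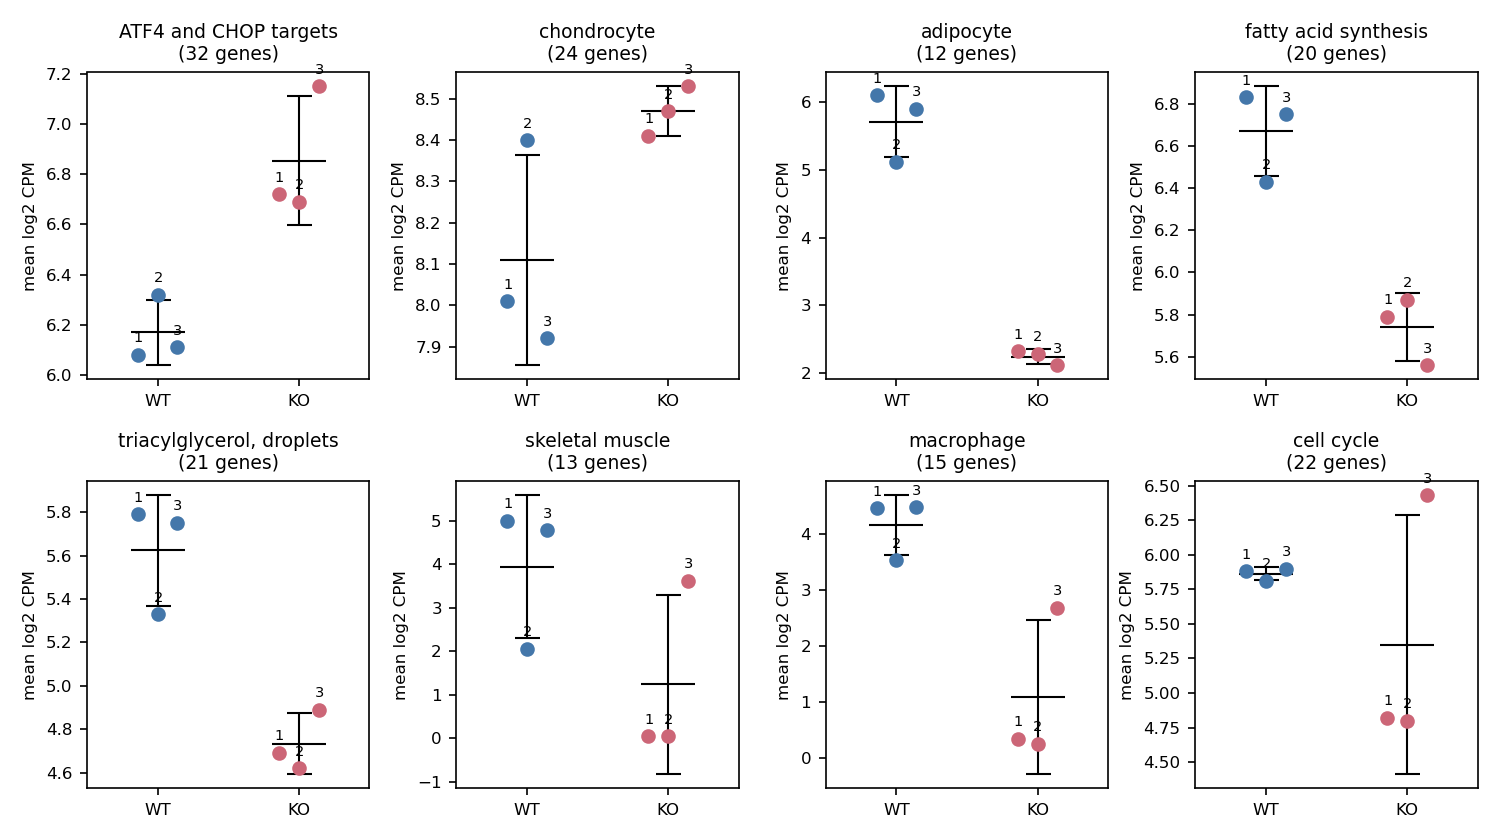
Mean log2 CPM of the tested members of 8 fixed lists per library (vertical axis, a separate scale per panel). Points are libraries with their replicate numbers, horizontal bars are group means and whiskers 1 SD (n = 3). The adipocyte mean is 5.71 in WT and 2.24 in KO, and KO replicate 3 lies apart from KO replicates 1 and 2 in the muscle (3.62), macrophage (2.68) and cell cycle (6.43) lists.

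Nuclear genes of the respiratory chain lay lower in 28 of 28 estimates, by a mean of 0.15 on the log2 scale. None passed the gene test (0 of 28 by either adjustment), and the list was called (camera adjusted p = 0.000387, adjusted p = 0.377 with an estimated correlation), with Atp5b at -0.16 (adjusted p = 0.409) and Atp5a1 at -0.07 (adjusted p = 0.642). Of the 28, 12 fell and 0 rose without KO replicate 3. Glycolysis and hypoxia genes were called lower (camera adjusted p = 0.00186, adjusted p = 0.549 with an estimated correlation) with 0 of 22 members called by either adjustment, Gapdh at -0.51 (adjusted p = 0.324) and Eno1 at -0.33 (adjusted p = 0.466). The call of the list: glycolysis and hypoxia, was lost without KO replicate 1 (camera adjusted p = 0.0627) or KO replicate 2 (0.0641), and without KO replicate 3 Gapdh fell (-0.82, adjusted p = 0.000279) among 21 of the 22 members (camera adjusted p = 1.1e-11, adjusted p = 0.536 with an estimated correlation). Of 22 cell cycle genes 0 were called by either adjustment and the list was not called (camera adjusted p = 0.0601), with Ccnd1 at -0.37 (adjusted p = 0.575) and the proliferation marker Mki67 at -0.55 (adjusted p = 0.666). The cell cycle list mean was 4.82 and 4.80 log2 CPM in KO replicates 1 and 2 and 6.43 in KO replicate 3, around 5.86 ± 0.0473 in WT (SD, n = 3). Without KO replicate 3, 19 of the 22 cell cycle genes fell (camera adjusted p = 5.41e-13, adjusted p = 0.536 with an estimated correlation). Over 17 alternatives the cell cycle list was past the threshold in 7 and its adjusted p ran from 5.41e-13 to 0.699, and for the list of glycolysis and hypoxia these were 13 and 1.1e-11 to 0.549.

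Icam1, an adhesion molecule of the inflammation and NF-kB list, fell (-1.03, SE 0.121, adjusted p = 0.0195), while 0 of the 11 tested members rose and 10 were not called, against 2 that fell and 0 that rose when adjusted over the list alone (camera adjusted p = 0.0601). The list: inflammation and NF-kB, was called lower without WT replicate 2 (camera adjusted p = 0.0106), KO replicate 2 (0.0295) or KO replicate 3 (0.0472, adjusted p = 0.536 with an estimated correlation, 6 members that fell and 1 that rose). For leave-outs other than KO replicate 3 an estimated correlation was not run. Of 25 lysosome and autophagy genes 0 were called, against 3 that rose and 0 that fell when adjusted over the list alone (camera adjusted p = 0.0601), with Ctsd at -0.15 (adjusted p = 0.766) and Lamp1 at 0.15 (adjusted p = 0.718). The list: lysosome and autophagy, was called higher without KO replicate 1 (camera adjusted p = 0.0417) or KO replicate 2 (0.0114), and without KO replicate 3 it was not called, with 5 members that rose and 3 that fell. Of 15 p53 targets and cell death genes 0 were called over all genes, against 1 that fell when adjusted over the list alone (camera adjusted p = 0.153), with Cdkn1a at -0.07 (adjusted p = 0.938) and Ccng1 at -0.34 (adjusted p = 0.508). The p53 list was called lower without KO replicate 3 (camera adjusted p = 0.00357, adjusted p = 0.536 with an estimated correlation), with 8 members that fell and 1 that rose. Of 16 interferon response genes 0 were called by either adjustment (camera adjusted p = 0.998), with Ifi27 at -0.16 (adjusted p = 0.614). The mean (0.23) and median (0.37) log2 fold change of the interferon list were above 0 while camera's direction was down, and without KO replicate 3 the list was called higher (camera adjusted p = 0.00199, adjusted p = 0.536 with an estimated correlation), with 10 members that rose and 0 that fell. Over 17 alternatives the lists of inflammation, lysosome, p53 and interferon genes were past the threshold in 5, 4, 3 and 3, with adjusted p from 0.00943 to 0.35, 0.0114 to 0.625, 0.00198 to 0.549 and 0.00199 to 1.0.

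Over the 28 lists tested, camera with a preset correlation of 0.01 called 16, 4 higher and 12 lower. With an estimated correlation 0 were called (smallest adjusted p = 0.35), and the rotation test fry called 10, of which 9 were among the 16. Fry lost the calls of the serine and glycine (adjusted p = 0.0662), synthetase (0.0797), glycolysis (0.383) and chondrocyte lists (0.23). Lost as well were those of fibroblast (0.254), skeletal muscle (0.23) and endothelium genes (0.21). The list that fry added was inflammation and NF-kB (0.0247). The other 9 splits of the same 6 libraries gave 2 to 14 lists by camera. Those splits mix WT and KO libraries within each group, so their counts do not show the level without any difference.

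For transcripts changed in KO, edgeR called 0 of 33288 tested, with 2526 at an unadjusted p under 0.05. Limma-voom called 0 (2946 at an unadjusted p under 0.05) and DESeq2 1741 (4423). Without WT replicate 2 edgeR called 2 transcripts, and without KO replicate 3 it called 304. Ppp1r15b was listed with 1 transcript, and its transcript counts were those of the gene.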

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

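The settings named here as added after seeing the data were robust quasi-likelihood, limma-voom with library quality weights, and WT replicate 2 and KO replicate 3 both left out; the others were planned. All 344 called genes kept their direction under each of the 16 settings in which they had a value (272 of them under the filter of at least 1 CPM in all 6 libraries). The groups did not overlap in any of the 344, so a kept direction was nearly fixed in advance and is no separate support. DESeq2 size factors gave 335 of the 344 again, library size only 292, limma-voom 264, robust quasi-likelihood 310, no filter on low counts 286 and the DESeq2 Wald test all 344. For genes lower in KO by the fold rule, genes higher in KO by the fold rule and transcripts changed in KO, values follow those of all genes. The DESeq2 Wald test called 497 genes higher and 674 lower (204 and 485 by the fold rule) and 1741 transcripts; the cause was not tested. The filter of at least 1 CPM in all 6 libraries called 148 genes lower (130 by the fold rule) among 12134 tested, and 27 transcripts, and no filter on low counts called 8 transcripts. Leaving out each library in turn gave 0 to 1731 genes higher and 0 to 2231 lower (0 to 488 and 0 to 1354 by the fold rule), 0 to 304 transcripts, and log2 fold changes of Ppp1r15b from -1.91 to -1.57. The 0 came without WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 2, and the highest counts without KO replicate 3. Counts simulated at the gene dispersions without KO replicate 3 had a common dispersion of 0.00817, against 0.053 at those of all 6 libraries. Limma-voom with library quality weights called 1918 genes higher and 2389 lower (493 and 1407 by the fold rule) and 37 transcripts. With WT replicate 2 and KO replicate 3 both left out 2416 genes were higher and 3000 lower (609 and 1691 by the fold rule), and 79 transcripts were called. Ppp1r15b was past the threshold in 11 of 16 settings, with adjusted p from 5.33e-13 to 0.173. The replicate number as a block gave 1 gene higher and 4 lower (1 and 4 by the fold rule) and a Ppp1r15b log2 fold change of -1.67 (edgeR adjusted p = 0.116). Deviations of same-numbered libraries correlated at -0.143, 0.215 and 0.238, and 1 of 3 WT libraries correlated best with its own number. With so few libraries, and WT replicate 2 and KO replicate 3 standing apart, these correlations cannot tell whether the numbers pair the samples. With an estimated correlation 0 lists were called and with fry 10, of which 9 were among the 16 of camera; camera allows for correlation between genes only as far as the preset value. The list: interferon response, turned from down to up in camera without KO replicate 3, with library quality weights (mean log2 fold change 0.47) and with WT replicate 2 and KO replicate 3 left out (0.48), and its mean ran from -0.0004846 to 0.57 over the leave-outs. Timp3 ran from -0.29 to 0.46 over the leave-outs, and was called lower without KO replicate 3 (-0.29) and with both left out (-0.21), and Igf2 was called higher with both left out (0.19). List tests on DESeq2 results and on the robust fit were not run. Among the 74 named genes, 48 of them called, 43 calls were lost under the block and 16 without WT replicate 2.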

Other observations

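The tests of explanations in this part were chosen after the results were seen, as were the genes named from outside the fixed lists. The amino acid transporter genes Slc38a1 (1.13, SE 0.162, edgeR adjusted p = 0.0297), Slc1a5 (0.68, SE 0.0661, adjusted p = 0.0149) and Slc1a4 (0.52, SE 0.0773, adjusted p = 0.0331) rose in KO, as did Mat2a, which makes S-adenosylmethionine (0.64, adjusted p = 0.0403). Irx3 rose from 11.2 ± 1.55 to 32.0 ± 4.23 CPM and Irx5 from 2.32 ± 0.186 to 5.54 ± 0.236 CPM (SD, n = 3 each), and both encode homeobox factors of limb patterning. The insulin-responsive glucose transporter gene Slc2a4 (-2.64), the complement gene C3 (-3.48), Apoe (-2.21), Gpat3 (-1.81) and the lipid sensor gene Nr1h3 (-1.05) fell. Tmsb4x (-0.90, SE 0.0748, adjusted p = 0.0127), Tmsb10 (-0.92, SE 0.0743, adjusted p = 0.0126), S100a10 (-0.80) and S100a11 (-0.73) fell as well, while S100a4 was not called (-0.95, adjusted p = 0.212). Without KO replicate 3, S100a4 fell too (-1.47, edgeR adjusted p = 3.4e-05).

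KO replicate 3 differed from KO replicates 1 and 2 by over 4-fold in 205 genes that were lower (of 11944 above 2 CPM) and 313 that were higher (of 12029). Sfrp2, a Wnt modulator, had 3310 and 3230 CPM in KO replicates 1 and 2 and 115 in KO replicate 3, against 1170, 1100 and 938 in WT. Ptn had 645, 608 and 21.1 CPM in KO replicates 1 to 3 (142, 90.6 and 106 in WT), and Igf1 163, 172 and 12.2 CPM (140, 88.4 and 112 in WT). In the other direction, Mki67 had 47.5, 57 and 211 CPM (153, 149 and 159 in WT). The immediate early gene Fos had 28, 26.9 and 186 CPM (9.86, 4.3 and 10.5 in WT). For Mki67, KO replicates 1 and 2 thus lay below WT and KO replicate 3 above it.

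A WT library under the label KO replicate 3 was argued against by Ppp1r15b, which stood at 52.7% of the lowest WT library, and by the adipocyte genes, of which 12 of 12 lay below their lowest WT library. Over 3885 of the 3962 genes called without this library, those also tested over all 6, it lay nearer to the other KO libraries in 41.5%. Those genes were chosen by the difference of KO replicates 1 and 2 from WT. Traits of that pair alone can lower the share, so it cannot decide the label of KO replicate 3. Added muscle cells and macrophages, whose genes were higher there (median log2 ratio 3.95 and 2.50 over 13 and 15 genes, among them Myh8, Ctss and Lyz2), could not give the genes that were over 4-fold lower, since chondrocyte genes were not diluted (median log2 ratio 0.0283, quartiles -0.212 and 0.314). Whether such cells may account for the higher cell cycle genes (median log2 ratio 1.83, quartiles 1.15 and 2.11) cannot be told apart from more division of the chondrocytes, because the cell cycle level of the added cells is not known; in WT replicate 2, where muscle genes were lower, cell cycle genes moved little (median log2 ratio -0.0854). A difference in culture stage or growth stays open and untested.

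WT replicate 2 lay between the other WT libraries and KO replicates 1 and 2 in many genes, Ppp1r15b among them. If RNA of such a KO culture had been mixed in, every list would stand at 1 position between those libraries, counted from 0 at WT to 1 at KO. Skeletal muscle genes stood at 0.882 (quartiles 0.876 and 0.912, 13 genes), adipocyte genes at 0.543 (0.521 and 0.61, 11 genes) and cell cycle genes at 0.109 (0.0704 and 0.153, 12 genes), which argues against a mixture as the whole cause. An equal loss of all other cells was argued against as well, since muscle genes (median log2 ratio -2.88, quartiles -3.10 and -2.78) and adipocyte genes (-0.845, quartiles -1.04 and -0.726) moved apart. A higher share of chondrocytes, whose genes were higher there (median log2 ratio 0.491, quartiles 0.319 and 0.577, 24 genes), with unequal losses of other cells stays open and untested.

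The fall of adipocyte genes may be a change in cell makeup, in expression per cell or both, and the loss of Ppp1r15b stays open as the cause of either. Whether all non-chondrocyte cells were lost alike could not be decided. With all libraries, 4 of 7 other cell types had quartile ranges of log2 fold change above that of the adipocyte genes (median -3.51, quartiles -5.74 and -1.48). Without KO replicate 3, 3 did (fibroblast, tendon and osteoblast, medians 0.087, -0.121 and 0.0981, against -3.32). In that setting muscle genes (median -4.89, quartiles -5.26 and -4.64) lay below smooth muscle genes (-1.14, quartiles -1.59 and -0.814). They also lay below endothelium genes (-1.80, quartiles -2.51 and -0.479). The muscle range overlapped that of macrophage genes (-4.71 and -3.44). The adipocyte range (-5.71 and -1.24) overlapped each of these. Equal losses would not part such ranges unless the sorted cells express some of the lists. Whether they do was not tested. If they do, these lists would not report a loss of other cells. The fibroblast list mean was high in both groups (8.34 log2 CPM in WT and 7.84 in KO). Muscle (median log2 ratio 3.95) and adipocyte genes (-0.361) moved apart between KO replicate 3 and the other KO libraries, but this rests on 1 library. A narrower version over 4 types, chosen after the count of 4 was seen, gave 1 with all libraries and 0 without KO replicate 3, and was dropped. A joint loss of fat, muscle and macrophage cells in KO replicates 1 and 2 stays open (medians -3.32, -4.89 and -4.32). A lower share of adipocyte-lineage cells, which the GFP sort would not remove, cannot be told apart from lower lipid gene expression per cell. Of the lipid genes that fell outside the adipocyte list, 11 stood in WT replicate 2 at a median position of 0.517 between the groups (quartiles 0.482 and 0.606), beside 0.543 for adipocyte genes, but Fads2 (-0.113) and Slc25a1 (0.223) stood apart, and only 1 WT library had a lower adipocyte level.

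The real grouping gave 344 called genes, and the highest of the other 9 splits of the 6 libraries gave 0, so that 1 of the 10 splits gave as many. For lists called by camera the real value was 16 and the highest other 14, again 1 of 10 splits, and for transcripts 0 and 0, so that 10 of 10 gave as many. With 10 splits the share cannot go under 0.1, so the splits are too few for a share under 0.05. Each other split also mixes WT and KO libraries within its groups. A difference between WT and KO would widen the spread there, so its counts do not show the level without any difference.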
